A study of Rattus norvegicus with 22 samples.

How the data were processed

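The material was CD4+ T cells of Lewis rats specific for myelin basic protein, in 3 states. T cell blasts were taken in culture on day 2 after antigen challenge (5 replicates), resting T cells in culture on day 7 (4 replicates), and spleen T cells were sorted ex vivo 3 days after adoptive transfer (2 replicates). Each replicate was hybridized to both Affymetrix rat genome array types of the set, here called array A and array B, which gave 22 arrays. Per the labels' protocols, RNA was isolated with a column kit and biotinylated cRNA was made from 6 ug of total RNA. The labels do not say whether replicates are separate cultures or animals, so p-values measure the spread between these samples. They also do not say that the A and B arrays of one number share RNA. Over 100 probe sets present on both types, deviations from the state mean correlated best with the array of the same number for every cultured replicate, with r from 0.56 to 0.97. The deviations of the 2 spleen replicates mirror each other, so their r of 0.55 is a single comparison.

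The files used were 2 value tables, 1 per array type, as deposited by the authors. The deposited values lie between 0.62 and 7.84 and have the shape of a log scale. How they were summarized and normalized, and the base and offset of the log, is not given in the sources used here. The column medians were 3.01 to 3.05 on array A and 2.76 to 2.79 on array B, and the distributions of the columns were not identical, so the tables were not quantile normalized as deposited. The signal of the hybridization controls from bioB to cre spanned 3.28 units on array A and 3.33 on array B, against 6.06 for their nominal amounts on a base 2 scale and 4.20 on a natural log scale, which leaves the base open. The design written before the data were examined assumed log2 values. The values were used as deposited, and every difference below is in deposited log units. A difference of 1 unit is 2-fold if the base is 2 and 2.72-fold if it is e. Folds below are computed for base 2 and written as "at least", which assumes a base of 2 or more. The number of arrays limits the precision, and no detection calls were used.

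Probe sets were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes). The 3 states of one array type entered 1 fit with no covariate, so that all states share 1 estimate of the spread, since the spleen state has 2 replicates. The 57 control probe sets of each type were left out, with no other filter, which left 15866 tested probe sets on array A and 15276 on array B. A probe set is called at a Benjamini-Hochberg adjusted p under 0.05 within its array type and comparison. Every adjusted p of a gene below comes from this limma fit. Gene symbols came from the platform annotation, updated through gene identifiers to the rat RefSeq genes of assembly GRCr8. On array A, 12783 probe sets had 1 symbol, 312 had several and 2771 had none. On array B these were 7564, 100 and 7612. No gene was named from a probe set with several symbols. The array types together measured 13810 genes, 2268 of them on both.

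Before the data were examined, 23 gene lists were fixed. Each gene counts once, by its probe set with the highest mean over the 11 arrays of its type, on array A where both types measure it. Calls of list members are given over all probe sets tested and "adjusted over the list alone", by Benjamini-Hochberg within the list. The shift of a list against all other genes was tested with camera of limma, with a preset inter-gene correlation of 0.01, for lists with at least 5 genes on an array type and Benjamini-Hochberg adjustment over the lists. Each camera value below is for array A unless array B is named. Camera was repeated with the correlation estimated from the data, and no list passed the threshold in any comparison then. That p is given beside each called list. Lists found with fry, a test of whether the genes move one way on balance, are counted as an alternative.

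The named genes follow a rule fixed before the data were examined. For each comparison they are the 6 genes with the largest positive and the 6 with the largest negative difference on array A and the 2 and 2 on array B, among probe sets with 1 gene symbol that were called and whose single array values do not overlap between the groups. Within each list up to 4 called members with the largest difference follow, of which the text gives some. A further fixed set of genes is given whether called or not, and part of it is not reported here. Values of a gene are the mean ± SD over arrays, and its difference carries the SE of the fit. Where probe sets of a gene disagree this is stated.

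The spleen state was placed between blast (0) and resting cells (1) by the mean difference of probe sets chosen on blast replicates 1, 3 and 5 and resting replicates 1 and 3, and measured on the other cultured replicates. The overlap of the spleen comparisons was set against independent lists and, at an unadjusted p under 0.05, against 100 simulated data sets with no change that share the spleen arrays. RNA quality was measured as the signal of 3 prime minus 5 prime control probe sets of actin and Gapdh, with hexokinase added later, and tested between resting cells and blasts with two-sided exact permutation tests. The 9 cultured samples were also split in other ways into 5 and 4, with 100 of the 126 splits drawn per array type.

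Alternatives were quantile normalization, centring on array medians, floors at the 20th and 40th percentile, leaving out the 40% dimmest probe sets, a trended and robust variance, a fit of only the compared states, array weights, the replicate number as a block, adjustment over both array types together, and leaving out each replicate in turn. For lists they were the median of a gene's probe sets, an estimated correlation and fry. No alternative was added after the data were examined.

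The fit was tested on simulated data with 200 changed probe sets among those of each array type. For resting cells against blasts on array A, 66% of changes of 0.25 units and 90% of changes of 0.5 units were recovered, with 3 false calls among 15666 unchanged probe sets. For spleen cells against blasts on array A these were 46% and 88% with 10 false calls, and for spleen against resting cells 36% and 90% with 9. On array B the recovery of changes of 0.5 units was 96%, 90% and 92% in the same order. The simulated noise was normal, independent between probe sets and had the spread of the fit. These rates therefore do not cover deviations that probe sets of an array share. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.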

Results

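Gene expression was measured in CD4+ T cells of Lewis rats that recognize myelin basic protein, in culture and after transfer into rats. The groups were T cell blasts on day 2 after antigen challenge (n = 5), resting T cells on day 7 of culture (n = 4), and T cells sorted from the spleen 3 days after adoptive transfer (n = 2). Each of the 11 samples was measured on array A and on array B. Within a state, arrays of type A correlated with r from 0.968 to 0.996 across probe sets and arrays of type B with r from 0.965 to 0.994, where probe sets are not independent replicates. All values are in the deposited log units, whose base is not given in the sources used here, and folds are for base 2 and are lower limits if the base is larger.

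Resting cells differed from blasts first of all by the loss of the proliferation program. Every one of the 38 measured genes of cell cycle and DNA replication was lower in resting cells. The largest falls were those of Rrm2, a subunit of ribonucleotide reductase, which fell by 2.82 ± 0.13 (SE; adjusted p = 1.95e-07, at least 7.04-fold), and of the cyclin Ccna2, which fell by 2.63 ± 0.15 (adjusted p = 1.11e-06). The transcription factor Tcf7, which marks quiescent and memory T cells, rose by 2.78 ± 0.15 (adjusted p = 3.21e-07, at least 6.88-fold), from 1.88 ± 0.28 (SD, n = 5) to 4.66 ± 0.26 (SD, n = 4). Enzymes of cholesterol synthesis, ribosome biogenesis and mitochondrial respiration were lower, and components of T cell identity were higher.

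Among the genes with the largest differences on array A, the chemokine Ccl5 rose by 2.72 ± 0.15 (adjusted p = 3.99e-07), Slfn5 of the Schlafen family by 2.65 ± 0.29, the protease inhibitor Serpinb1a by 1.88 ± 0.18 and Ypel3, a growth suppressor, by 1.77 ± 0.26. The fatty acid binding protein Fabp5 fell by 3.30 ± 0.16 (adjusted p = 1.47e-07, at least 9.87-fold) and Psat1, an enzyme of serine synthesis, fell by 2.97 ± 0.14. The mitotic regulators Cdkn3, Cks2 and Ube2c and the replication factor Pclaf fell by 2.50, 2.42, 2.32 and 2.32. On array B the prothrombinase Fgl2 rose by 2.00 ± 0.33 and the lysophosphatidic acid receptor Lpar6 by 1.84 ± 0.12. For Klf2, a transcription factor of quiescence and T cell trafficking, the probe sets disagreed. One rose by 1.91 ± 0.27 (adjusted p = 0.000201) and another by 1.17 (adjusted p = 0.00357), and the brightest one had a difference of 0.08 ± 0.11 (adjusted p = 0.617).

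The proliferation marker Mki67 fell by 1.77 ± 0.10 (adjusted p = 5.45e-07), with all 38 cell cycle genes also called when adjusted over the list alone. Camera gave an adjusted p of 6.35e-27 for this list, and an adjusted p = 0.184 with an estimated correlation. In cholesterol synthesis 20 of 22 genes were lower and none was higher, or 21 adjusted over the list alone (camera adjusted p = 9.81e-12, adjusted p = 0.486 with an estimated correlation). Its isomerase Idi1 fell by 1.90 ± 0.13, the desaturase Scd by 1.67 ± 0.11 and the farnesyl diphosphate synthase Fdps by 1.63 ± 0.10, and Scd belongs to fatty acid rather than sterol synthesis. In ribosome biogenesis 28 of 30 were lower, 29 adjusted over the list alone, and none was higher (camera adjusted p = 9.39e-09, adjusted p = 0.514 with an estimated correlation). Here Nhp2 of the box H/ACA particle fell by 1.59 ± 0.19 and fibrillarin (Fbl) by 1.32 ± 0.09. In mitochondrial respiration 27 of 30 were lower and 1 was higher, over all probe sets and adjusted over the list alone (camera adjusted p = 6.07e-09, adjusted p = 0.486 with an estimated correlation), among them the ATP synthase subunit Atp5f1b, which fell by 0.90 ± 0.08, and cytochrome c1 (Cyc1), which fell by 0.89 ± 0.08.

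In the list of unfolded protein response and amino acid supply, 17 of 28 genes were lower and 2 higher, 19 and 2 adjusted over the list alone (camera adjusted p = 0.000415, adjusted p = 0.514 with an estimated correlation). The members with the largest falls make serine and one-carbon units rather than chaperones: Psat1, Phgdh, which fell by 1.61 ± 0.09, and Shmt2, which fell by 1.60 ± 0.15. In glycolysis and glucose uptake 11 of 20 were lower and 1 higher, 12 and 1 adjusted over the list alone (camera adjusted p = 0.00606, adjusted p = 0.514 with an estimated correlation). The lactate transporters Slc16a1 and Slc16a3 fell by 0.72 ± 0.16 and 0.70 ± 0.17, and the glucose transporter Slc2a3 rose by 0.67 ± 0.13. Camera lost this list under quantile normalization (adjusted p = 0.0614).

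Quiescence and growth restraint had 16 of 24 genes higher and 2 lower, 18 and 2 adjusted over the list alone (camera adjusted p = 0.000124, adjusted p = 0.486 with an estimated correlation). The thioredoxin inhibitor Txnip rose by 1.72 ± 0.23 and the interleukin 7 receptor Il7r by 1.38 ± 0.12, while Klf4 had 2.56 ± 0.09 (SD, n = 4) in resting cells and 2.46 ± 0.17 (SD, n = 5) in blasts (adjusted p = 0.444). T cell identity had 14 of 21 higher and 1 lower, 17 and 1 adjusted over the list alone (camera adjusted p = 9.96e-05, adjusted p = 0.497 with an estimated correlation). Bcl11b was up by 1.08 ± 0.11, Ptprcap, which binds CD45, by 0.99 ± 0.11 and Cd4 by 0.75 ± 0.10. Blast replicate 5 lay outside the range of the other blasts on array A in the list means of quiescence, T cell identity, ribosome biogenesis and cell cycle genes, and inside it for cholesterol synthesis and respiration. On the scale from the other blasts (0) to resting cells (1) it lay at 0.59 for quiescence, 0.557 for T cell identity, 0.753 for ribosome biogenesis, 0.137 for cell cycle, 0.0958 for cholesterol synthesis and 0.0278 for respiration on array A.

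Trafficking receptors had 7 of 19 members higher and none lower, the same counts adjusted over the list alone. Their mean difference on array A was 0.25, which camera did not call (adjusted p = 0.117) and fry did (adjusted p = 0.00262). The chemokine receptors Ccr3, Cxcr3, Ccr6 and Ccr2 rose by 1.17 ± 0.16, 1.12 ± 0.20, 1.06 ± 0.14 and 0.98 ± 0.15, and S1pr1, the receptor for lymphoid egress, rose by 0.87 ± 0.18 (adjusted p = 0.00296) in its brightest probe set and differed by -0.02 (adjusted p = 0.734) in the other. Cxcr4 was at 4.73 ± 0.51 (SD, n = 4) in resting cells and 5.23 ± 0.27 (SD, n = 5) in blasts (adjusted p = 0.0901, and 0.0365 without resting replicate 1). Integrins and adhesion molecules had 11 of 30 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.0501). Camera called this list under quantile normalization (0.0461), median centring (0.036), array weights (0.0371), the replicate block (0.0275), a floor at the 40th percentile (0.0441), with only the 2 states in the fit (0.0469) and by the median of a gene's probe sets (0.0353). It did so too without blast replicate 3, 4 or 5, resting replicate 1 or either spleen replicate (0.0272 to 0.0491), as did fry (0.00275). Among them were the integrin beta chains Itgb1, up by 0.97 ± 0.15, and Itgb2, up by 0.90 ± 0.14, and the adhesion receptor Cd2, up by 1.09 ± 0.18. Ninj1, an adhesion molecule of leukocytes and nerve, fell by 0.30 ± 0.05 (adjusted p = 0.000714). Cytoskeleton and cell motility had 8 of 37 higher and 4 lower, also adjusted over the list alone (camera adjusted p = 0.13). Without blast replicate 5 there were 15 higher (camera adjusted p = 0.0251), and under quantile normalization 19 (0.00117), and camera called the list with the replicate block (0.00737). The galectin Lgals3 fell by 0.75 ± 0.08 and the calcium-binding S100a6 rose by 1.29 ± 0.32.

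T cell activation genes went both ways, with 6 of 25 higher and 6 lower, also adjusted over the list alone. Camera gave it an adjusted p of 0.859 with a positive sign, although its mean was -0.10 and its median -0.01. The transferrin receptor Tfrc fell by 1.97 ± 0.24, Myc by 1.03 ± 0.26 and Il2ra by 0.60 ± 0.14, and the adhesion receptor Cd44 and the early activation marker Cd69 rose by 1.04 ± 0.14 and 1.01 ± 0.13. Nr4a1 was at 3.48 ± 0.17 (SD, n = 4) against 3.29 ± 0.13 (SD, n = 5; adjusted p = 0.207). Of 24 cytokines and chemokines 4 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.585; mean 0.14, median -0.01). Ccl3 rose by 1.51 ± 0.17 and Ltb (lymphotoxin beta) by 1.27 ± 0.26, Il17f fell by 1.72 ± 0.26, and Ifng was at 4.07 ± 0.56 (SD, n = 4) against 3.64 ± 0.27 (SD, n = 5; adjusted p = 0.176, and 0.00408 without resting replicate 4). Of 30 interferon response genes 8 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.576; mean 0.11, median -0.03). Irf1 was up by 0.90 ± 0.10 and Gbp2 by 0.74 ± 0.15. The 8 became 5 without resting replicate 3 or 4.

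Of 23 cell death regulators 6 were higher and 1 lower, 5 and 1 adjusted over the list alone (camera adjusted p = 0.117). Pdcd4 was up by 0.92 ± 0.17, Mcl1 up by 0.55 ± 0.07 and the inflammatory caspase Casp4 down, by a difference of -0.86 ± 0.11. Immediate early and stress genes had 6 of 24 higher and 6 lower, 8 and 6 adjusted over the list alone (camera adjusted p = 0.585). The chaperonins Hspe1 and Hspd1 fell by 1.39 ± 0.14 and 1.26 ± 0.15, and Zfp36, which destabilizes cytokine mRNA, rose by 0.85 ± 0.16. Among markers of other cell types, called higher and lower were 1 and 0 of 16 B cell markers (none adjusted over the list alone; Btk, up by 0.10 ± 0.03, with adjusted p from 0.0532 to 0.118 without blast replicate 1, 3 or 4 or any 1 resting replicate), 2 and 0 of 28 myeloid markers (the protease Ctss, up by 0.87 ± 0.12, and Apoe, up by 0.84 ± 0.14), 0 and 1 of 8 MHC class II genes (Cd74, which fell by 0.71 ± 0.13), 0 and 1 of 13 erythroid and platelet markers (Epor, which fell by 0.47 ± 0.09), 4 and 2 of 17 NK and CD8 T cell markers, 3 and 0 of 9 thymocyte markers and 1 and 2 of 23 stroma and endothelium markers. Apart from B cell markers, these counts were the same adjusted over the list alone. The NK list included Nkg7, which fell by 1.67 ± 0.17, and Klrd1, which rose by 0.55 ± 0.13 (adjusted p = 0.0579 with a floor at the 40th percentile). The thymocyte list included Arpp21 and Tcf12, up by 0.79 ± 0.08 and 0.42 ± 0.07, and the stroma list Kdr, a receptor for VEGF, which fell by 1.39 ± 0.10, and Pecam1, up by 0.27 ± 0.05. Other probe sets of Apoe (0.00, adjusted p = 0.971), Kdr on array B (0.02, adjusted p = 0.796), Tcf12 (0.09, adjusted p = 0.454), Arpp21 (0.08, adjusted p = 0.422), Epor on array B (-0.08, adjusted p = 0.104), Slc16a1 on array B (-0.08, adjusted p = 0.132) and Pdcd4 on array B (0.12, adjusted p = 0.0782) were not called.

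Fry also called cytokines (adjusted p = 0.0104), cell death regulators (0.0245) and thymocyte markers (0.00285) higher and stroma markers (0.0104) lower on array A. On array B fry called T cell activation (0.0309), trafficking receptors (0.0309) and cytoskeleton (0.0174), and camera called interferon response without resting replicate 1 (0.046). In all, 3086 of 15866 probe sets on array A were called higher in resting cells and 2808 lower, of which 129 and 251 by at least 1 unit, and on array B 1645 of 15276 were higher and 1647 lower, of which 43 and 122 by at least 1 unit. The 3 prime minus 5 prime signal of Gapdh was larger in resting cells than in blasts, by 0.0586 on array A (two-sided exact p = 0.0397, Benjamini-Hochberg adjusted p = 0.119) and by 0.0971 on array B (exact p = 0.00794, the smallest possible, adjusted p = 0.0476), and actin and hexokinase gave exact p between 0.0714 and 0.611. Spleen arrays had a Gapdh value of 0.463 ± 0.130 (SD, n = 2) on array A and 0.389 ± 0.0704 (SD, n = 2) on array B.

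**Figure D1:**
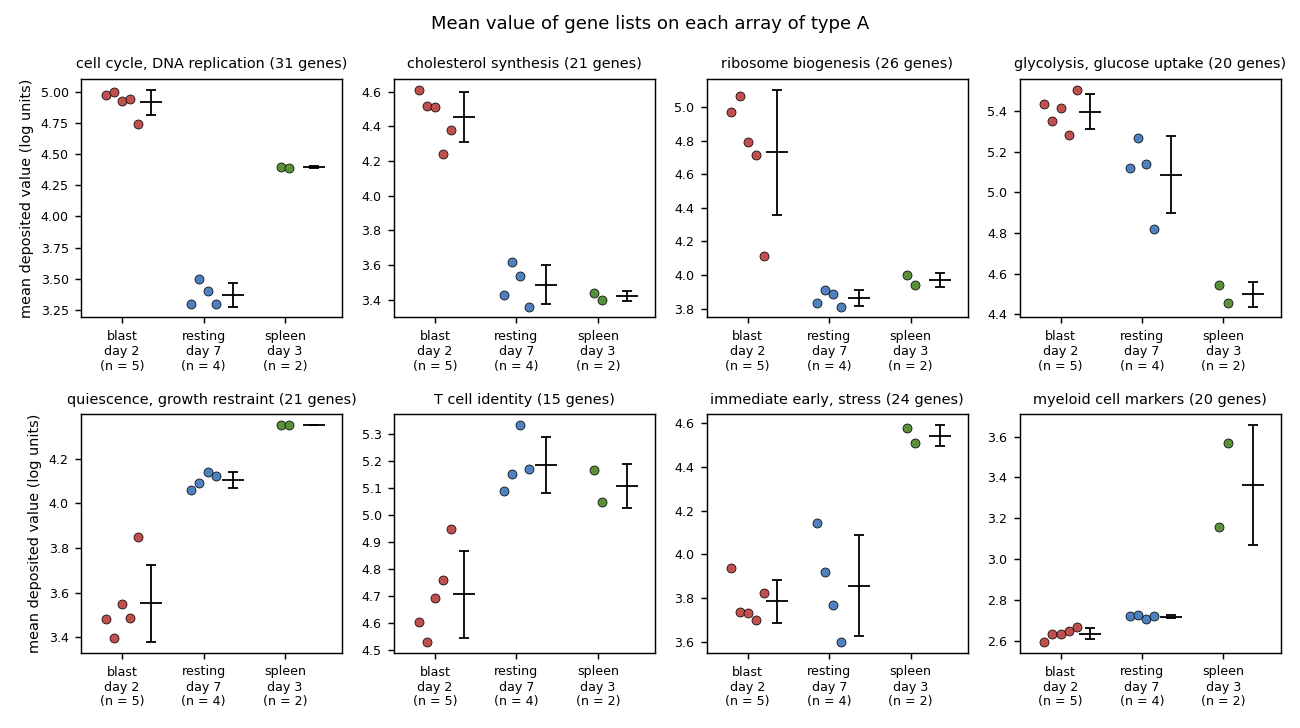
Mean deposited value (log units) of the members of 8 gene lists on each array of type A, by state, with points for arrays and bars for the mean ± SD over arrays. Spleen cells lie near resting cells for cholesterol synthesis and ribosome biogenesis, between the cultured states for cell cycle genes, and beyond both for glycolysis, immediate early genes and myeloid markers.

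Cells recovered from the spleen set themselves apart from blasts by lower genes of cholesterol synthesis (20 of 22), glycolysis (17 of 20) and cell cycle (31 of 38) and higher genes of quiescence (18 of 24). The probe sets of Klf2 disagreed in size, with 3.43 ± 0.33 (SE; adjusted p = 4.33e-05, at least 10.7-fold) in 1, 2.69 in another, 0.75 ± 0.13 (adjusted p = 0.00197) in the brightest, 0.21 (adjusted p = 0.0134) and 0.01 (adjusted p = 0.941). Tcf7 was higher by 3.40 ± 0.19 (adjusted p = 1.18e-06), at 5.28 ± 0.10 (SD, n = 2) against 1.88 ± 0.28 (SD, n = 5). The egress receptor S1pr1 was higher by 1.66 ± 0.23 (adjusted p = 0.000394, at least 3.16-fold) in its brightest probe set, against 0.09 (adjusted p = 0.225) in the other. Glycolytic enzymes were lower, led by Tpi1 with a difference of -1.91 ± 0.18 (adjusted p = 4.19e-05). Many markers of other cell types were also higher in the spleen samples, with 20 of 28 myeloid, 11 of 17 NK and CD8, 7 of 16 B cell and 5 of 13 erythroid and platelet markers called.

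Other large differences on array A were those of S100a9, a neutrophil and monocyte protein (3.36 ± 0.11), the galectin Lgals1 (2.94 ± 0.24), the beta globin Hbb (2.82 ± 0.16) and Plac8 (2.77 ± 0.11). Lower were Fabp5 (-2.22 ± 0.20), the CD30 gene Tnfrsf8 (-1.91 ± 0.19), Calca (-1.90 ± 0.37), which encodes calcitonin and CGRP, Bnip3 (-1.89 ± 0.24), a mitophagy receptor, and the mitochondrial adenylate kinase Ak4 (-1.89 ± 0.18). On array B, Cd69 was higher by 2.29 ± 0.16 and Rap1gap2, which inactivates the GTPase Rap1, by 2.28 ± 0.05 (adjusted p = 5.3e-10), and Pdk4, a pyruvate dehydrogenase kinase, and the lipoxygenase Aloxe3 were lower (-1.90 ± 0.23 and -1.85 ± 0.19).

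Quiescence and growth restraint had 18 of 24 genes higher and 1 lower, also adjusted over the list alone (camera adjusted p = 1.59e-09, adjusted p = 0.118 with an estimated correlation). The glucocorticoid-induced Tsc22d3 was higher by 1.88 ± 0.09, Klf3 by 1.47 ± 0.08, the antiproliferative Tob1 by 1.21 ± 0.08, Il7r by 0.93 ± 0.15 and Klf4 by 0.92 ± 0.11 (adjusted p = 0.000172). Of 38 cell cycle genes 31 were lower and none higher, 33 adjusted over the list alone (camera adjusted p = 1.35e-11, adjusted p = 0.153 with an estimated correlation). Cenpf (-1.01 ± 0.09), Rrm2 (-0.94 ± 0.16) and the helicase subunit Mcm6 (-0.93 ± 0.12) led it, and Mki67 was at 5.09 ± 0.03 (SD, n = 2) against 5.29 ± 0.17 (SD, n = 5; adjusted p = 0.297).

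Glycolysis and glucose uptake had 17 of 20 genes lower and 1 higher, 19 and 1 adjusted over the list alone (camera adjusted p = 1.45e-09, adjusted p = 0.118 with an estimated correlation), among them Slc16a3 (-1.83 ± 0.21) and the pyruvate dehydrogenase kinase Pdk1 (-1.69 ± 0.17). Cholesterol synthesis had 20 of 22 lower and none higher, 21 adjusted over the list alone (camera adjusted p = 5.9e-14, adjusted p = 0.118 with an estimated correlation). The methylsterol oxidase Msmo1 was at -1.87 ± 0.14 and Fdps at -1.81 ± 0.13. Ribosome biogenesis had 23 of 30 lower and none higher, 29 adjusted over the list alone (camera adjusted p = 4.04e-08, adjusted p = 0.304 with an estimated correlation), and Fbl fell by 1.00 ± 0.12. Without spleen replicate 1 its count of lower genes was 10, and without spleen replicate 2 it was 4. Mitochondrial respiration had 13 of 30 lower and none higher, 15 and 1 adjusted over the list alone (camera adjusted p = 0.000528, adjusted p = 0.363 with an estimated correlation). Cyc1 was at -0.60 ± 0.10. There were 4 lower members without spleen replicate 2. Amino acid supply and unfolded protein response had 11 of 28 lower and 5 higher, 15 and 5 adjusted over the list alone (camera adjusted p = 0.0294, adjusted p = 0.449 with an estimated correlation, 0.0505 under quantile normalization, 0.0952 without the 40% dimmest probe sets, 0.0578 with fry and 0.11 without spleen replicate 2). The asparagine synthetase Asns was lower (-1.84 ± 0.16), as were Psat1 (-1.49 ± 0.18) and Shmt2 (-1.37 ± 0.18), and the endoplasmic reticulum chaperone Dnajb9 was higher by 1.15 ± 0.10. The count of lower genes in this list was 7 without either spleen replicate and 17 without blast replicate 5.

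Trafficking receptors had 9 of 19 genes higher and none lower, 10 adjusted over the list alone (camera adjusted p = 0.000191, adjusted p = 0.101 with an estimated correlation). There were 4 higher members without spleen replicate 2. Ccr2 was higher by 1.42 ± 0.19 (adjusted p = 0.000299) and Cxcr4 by 1.13 ± 0.26 (adjusted p = 0.00865, not called without either spleen replicate, with adjusted p = 0.0741 and 0.0557). Cxcr3 was at 5.76 ± 0.11 (SD, n = 2) against 5.30 ± 0.47 (SD, n = 5; adjusted p = 0.228, and 0.00515 with the replicate number as a block). Integrins and adhesion molecules had 15 of 30 higher and 2 lower, 17 and 3 adjusted over the list alone (camera adjusted p = 7.86e-05, adjusted p = 0.118 with an estimated correlation). There were 7 higher members without spleen replicate 2. The integrin chains Itgb7, Itgb1 and Itgb3 were higher by 1.71 ± 0.29, 1.58 ± 0.19 and 1.19 ± 0.12, and Ninj1 was at 3.11 ± 0.03 (SD, n = 2) against 3.27 ± 0.09 (SD, n = 5; adjusted p = 0.0856, and 0.0214 without blast replicate 5). Cytoskeleton and cell motility had 20 of 37 higher and 1 lower, 25 and 2 adjusted over the list alone (camera adjusted p = 1.07e-07, adjusted p = 0.247 with an estimated correlation). S100a11 was up by 2.47 ± 0.21 beside Lgals1. There were 7 higher members without spleen replicate 1.

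T cell activation had 8 of 25 genes higher and 4 lower, 8 and 6 adjusted over the list alone (camera adjusted p = 0.334, fry 0.00201), with 7 lower without blast replicate 5. Its members on array B shifted up (camera adjusted p = 0.0252, adjusted p = 0.174 with an estimated correlation, and 0.0542 under quantile normalization). Nr4a1, an early target of T cell receptor signals, was higher by 2.34 ± 0.13 (adjusted p = 1.2e-06), and Tnfrsf4 (OX40) was lower (-1.38 ± 0.19). Il2ra was at 4.38 ± 0.16 (SD, n = 2) against 4.76 ± 0.33 (SD, n = 5; adjusted p = 0.146, and 0.0145 without blast replicate 4) and Myc at 4.09 ± 0.10 (SD, n = 2) against 4.90 ± 0.61 (SD, n = 5; adjusted p = 0.0959, and 0.000875 without blast replicate 5). Of 24 cytokines and chemokines 6 were higher and 2 lower, 7 and 3 adjusted over the list alone (camera adjusted p = 0.108, 0.0456 with a floor at the 40th percentile, 0.0404 without the 40% dimmest probe sets, and 0.000547 with fry). The chemokines Ccl5, Ccl3 and Ccl4 were higher by 2.42 ± 0.19, 1.70 ± 0.21 and 1.55 ± 0.12, and Ifng by 0.95 ± 0.28 (adjusted p = 0.0282, not called without either spleen replicate, with adjusted p = 0.118 and 0.158, or with the floors, with 0.0633 and 0.0748). Of 30 interferon response genes 7 were higher and none lower, also adjusted over the list alone, and 12 were higher without blast replicate 5 (camera adjusted p = 0.0411, adjusted p = 0.399 with an estimated correlation). Fry did not call this list (adjusted p = 0.0685). Camera lost it with the floors (0.0567 and 0.0686), without the 40% dimmest probe sets (0.0952), with only the 2 states in the fit (0.0679), without blast replicate 2 or 3 (0.0619 and 0.0709), without resting replicate 1 or 3 (0.0524 and 0.0536) and without spleen replicate 1 (0.114). Gbp2 was up by 1.15 ± 0.18 and Rsad2 by 0.64 ± 0.08 (adjusted p = 0.139 with a floor at the 40th percentile). T cell identity had 11 of 21 higher and none lower, 13 adjusted over the list alone (camera adjusted p = 7.86e-05, adjusted p = 0.25 with an estimated correlation). Ptprcap was up by 0.84 ± 0.14 and Cd5 by 0.79 ± 0.14. The 11 became 6 without spleen replicate 1 and 7 without spleen replicate 2 or blast replicate 1 or 3. Cd4 was at 4.82 ± 0.08 (SD, n = 2) against 4.67 ± 0.20 (SD, n = 5; adjusted p = 0.431, and 0.022 with the block). Of 23 cell death regulators 3 were higher and 3 lower, 4 and 4 adjusted over the list alone (camera adjusted p = 0.195). Casp4 was at -1.22 ± 0.13 and Mcl1 up by 0.64 ± 0.08. There were 6 higher members without blast replicate 5.

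Immediate early and stress genes had 14 of 24 members higher and 3 lower, 14 and 4 adjusted over the list alone (camera adjusted p = 7.43e-06, adjusted p = 0.153 with an estimated correlation). Fosb was higher by 2.55 ± 0.37 and the phosphatase Dusp1 by 1.85 ± 0.13. Myeloid markers had 20 of 28 members higher and none lower, 25 adjusted over the list alone (camera adjusted p = 1.21e-08, adjusted p = 0.199 with an estimated correlation). There were 10 higher members without spleen replicate 2. Beside S100a9, the lysozyme Lyz2 was higher by 2.28 ± 0.21 and Fcer1g by 1.56 ± 0.17. MHC class II antigen presentation had 4 of 8 higher and none lower, 5 adjusted over the list alone (camera adjusted p = 0.000393, adjusted p = 0.247 with an estimated correlation). RT1-Da was up by 2.12 ± 0.24 and RT1-Bb by 1.62 ± 0.11, with 0.00 (adjusted p = 0.987) in the other RT1-Bb probe set. B cell markers had 7 of 16 higher and none lower, 10 adjusted over the list alone (camera adjusted p = 6.02e-06 on array B, adjusted p = 0.174 with an estimated correlation). Ms4a1 (CD20) was up by 0.68 ± 0.13. There were 4 higher members without spleen replicate 2. Erythroid and platelet markers had 5 of 13 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.00409, adjusted p = 0.247 with an estimated correlation, and 0.0907 without the 40% dimmest probe sets). The erythroid heme enzyme Alas2 was up by 0.74 ± 0.09. There were 3 higher members without spleen replicate 2.

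NK and CD8 T cell markers had 11 of 17 members higher and 1 lower, 14 and 1 adjusted over the list alone (camera adjusted p = 1.46e-07, adjusted p = 0.118 with an estimated correlation). There were 7 higher members without spleen replicate 2. Klrd1 was higher by 2.36 ± 0.16 and Klrb1a by 1.08 ± 0.16 (adjusted p = 0.139 with a floor at the 40th percentile). Thymocyte markers had 6 of 9 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 1.58e-05, adjusted p = 0.101 with an estimated correlation). Cd1d1 was up by 1.38 ± 0.09 and Satb1 at -0.51 ± 0.07. There were 2 higher members without spleen replicate 2. Of 23 stroma and endothelium markers 2 were higher and 1 lower, 1 and 1 adjusted over the list alone (camera adjusted p = 0.271 with a positive sign, against a mean of -0.02). Kdr was at -1.30 ± 0.12 and Pecam1 up by 0.25 ± 0.07 (adjusted p = 0.0147, not called without either spleen replicate, with adjusted p = 0.0792 and 0.101). Other probe sets of Kdr on array B (0.03, adjusted p = 0.741) and of Calca (-0.36, adjusted p = 0.162) were not called.

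On array A 1922 probe sets were called higher in spleen cells than in blasts and 2377 lower, and on array B 820 and 1416. Without spleen replicate 1 the counts on array A were 1228 and 1492 and without spleen replicate 2 they were 1171 and 1228. On array B 485 were lower without spleen replicate 1 and 406 higher without spleen replicate 2. On array B camera called neither interferon response (adjusted p = 0.24, and 0.045 without spleen replicate 1) nor erythroid and platelet markers (adjusted p = 0.95, with a negative sign). Of the called probe sets on array B 36.7% were higher, and 48% under quantile normalization.

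**Figure D2:**
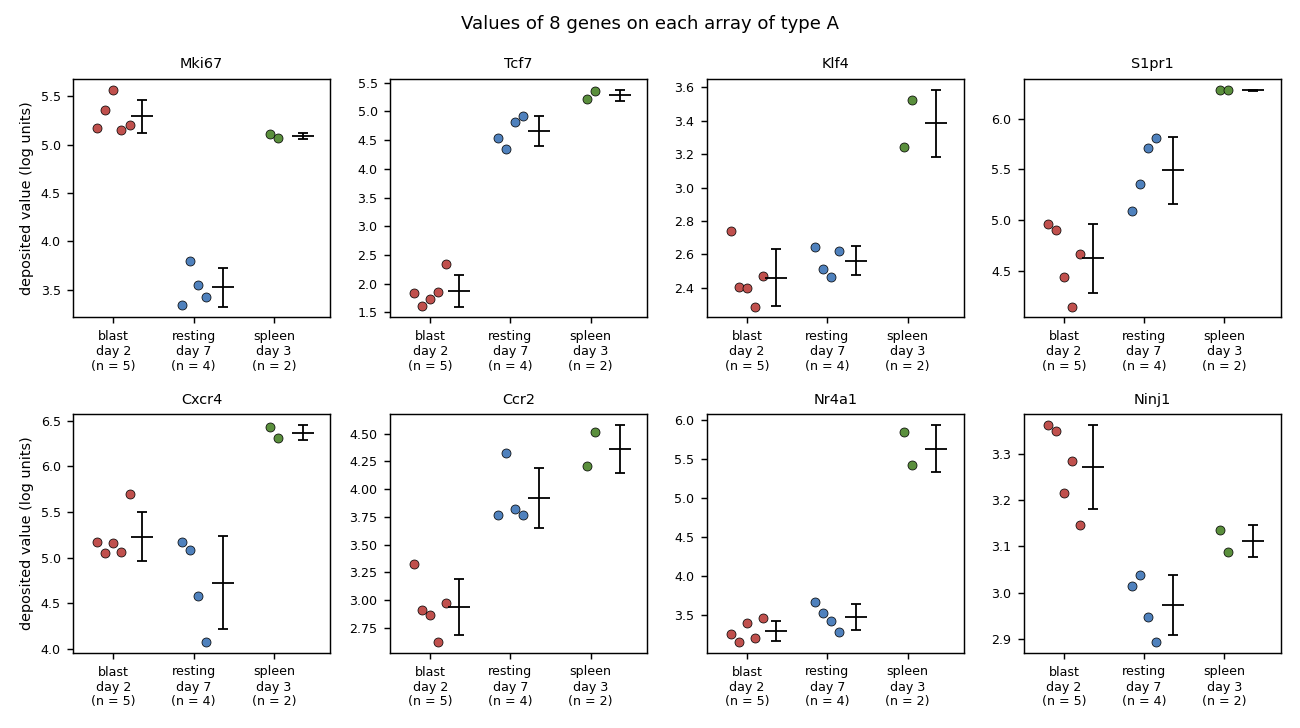
Deposited value (log units) of Mki67, Tcf7, Klf4, S1pr1, Cxcr4, Ccr2, Nr4a1 and Ninj1 on each array of type A, by state, with points for arrays and bars for the mean ± SD over arrays. Mki67 of spleen cells lies at 5.09 ± 0.03, near blasts. Both spleen values of Nr4a1, Cxcr4, Klf4, S1pr1 and Tcf7 lie above every cultured array.

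Against resting cells, spleen cells showed an active cell cycle program, with all 38 measured members higher. Cdkn3 was higher by 2.36 ± 0.15 (SE; adjusted p = 3.18e-06, at least 5.15-fold), the cyclin Ccnb2 by 2.03 ± 0.13 (adjusted p = 3.32e-06), Rrm2 by 1.88 ± 0.17 and Mki67 by 1.56 ± 0.13 (adjusted p = 2.82e-05), from 3.53 ± 0.20 (SD, n = 4) to 5.09 ± 0.03 (SD, n = 2). Glycolytic genes were lower still than in resting cells. Nr4a1 was higher by 2.16 ± 0.13 (adjusted p = 2.57e-06, at least 4.46-fold) and Cxcr4 by 1.64 ± 0.27 (adjusted p = 0.00239). Called higher were also 16 of 28 myeloid, 11 of 17 NK and CD8, 4 of 16 B cell and 3 of 13 erythroid and platelet markers.

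The largest differences on array A were S100a9 (3.32 ± 0.11, adjusted p = 7.24e-08), Hbb (2.83 ± 0.17), Plac8 (2.71 ± 0.12), S100a8 (2.48 ± 0.12), the partner of S100a9, and Lgals1 (2.44 ± 0.25). Lower were Calca (-2.69 ± 0.38), the prolyl hydroxylase P4ha1 (-1.74 ± 0.17), the creatine kinase Ckb (-1.70 ± 0.28), Ociad2 (-1.67 ± 0.32), the syndecan Sdc1 (-1.67 ± 0.06) and Ak4 (-1.64 ± 0.18). On array B, Rap1gap2 was higher by 2.25 ± 0.05, and Pdk4 (-1.58 ± 0.23) and the growth factor receptor Igf1r (-1.34 ± 0.11) were lower.

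The 38 cell cycle genes were also higher adjusted over the list alone (camera adjusted p = 8.85e-33, adjusted p = 0.109 with an estimated correlation), with a mean difference of 1.02 over the genes on array A. Glycolysis and glucose uptake had 14 of 20 lower and 1 higher, 15 and 1 adjusted over the list alone (camera adjusted p = 2.97e-08, adjusted p = 0.185 with an estimated correlation). Bnip3 was at -1.55 ± 0.24, Tpi1 at -1.33 ± 0.19 and Pdk1 at -1.11 ± 0.17. The list had 9 lower genes without spleen replicate 1 and 8 without spleen replicate 2. Cholesterol synthesis had 1 of 22 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.371), where Idi1 was higher by 0.63 ± 0.17 and the epoxidase Sqle lower (-0.51 ± 0.13), neither of them called without spleen replicate 1 or without spleen replicate 2 (adjusted p = 0.144 and 0.155 for Idi1, 0.144 and 0.102 for Sqle) or with the floors (0.0687 and 0.0816, 0.0516 and 0.0618). Idi1 was also not called without resting replicate 1 or 4 (adjusted p = 0.0613 and 0.0643). Of 30 ribosome biogenesis genes none was called in limma, over all probe sets or adjusted over the list alone (camera adjusted p = 0.354). With only the 2 states in the fit camera called the list higher (adjusted p = 0.0187, mean 0.11). At an unadjusted p under 0.05 there were 2 higher, and 6 were called higher without blast replicate 5.

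Mitochondrial respiration had 8 of 30 genes higher and none lower, 16 and 1 adjusted over the list alone (camera adjusted p = 2.76e-05, adjusted p = 0.338 with an estimated correlation). Atp5f1b was up by 0.42 ± 0.10 (adjusted p = 0.181 without spleen replicate 1). Without spleen replicate 1 none was called higher, and without resting replicate 1 or 4 there were 5. In amino acid supply and unfolded protein response 9 of 28 were higher and 2 lower, 10 and 3 adjusted over the list alone (camera adjusted p = 0.00344, adjusted p = 0.42 with an estimated correlation, 0.0969 with fry), and 3 were higher without spleen replicate 1. Psat1 was higher by 1.49 ± 0.18 and the stress factor Ddit3 by 0.60 ± 0.09. Quiescence and growth restraint had 9 of 24 higher and 1 lower, 9 and 3 adjusted over the list alone (camera adjusted p = 0.00281, adjusted p = 0.351 with an estimated correlation). Tsc22d3 was up by 1.17 ± 0.10, Tob1 by 0.96 ± 0.09 and Klf4 by 0.82 ± 0.12 (adjusted p = 0.000833). The brightest Klf2 probe set was higher by 0.67 ± 0.14 (adjusted p = 0.00762, and 0.112 without spleen replicate 2), against 1.52 and 1.52 in 2 others and 0.06 (adjusted p = 0.433) and 0.12 (adjusted p = 0.189) in the last 2. Il7r was at 4.10 ± 0.08 (SD, n = 2) against 4.54 ± 0.16 (SD, n = 4; adjusted p = 0.0844, 0.0324 without blast replicate 4 and 0.0166 with only the 2 states in the fit). Its probe set on array B was lower (-0.61 ± 0.12, adjusted p = 0.0102).

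Trafficking receptors had 6 of 19 genes higher and 3 lower, 7 and 4 adjusted over the list alone. There were 2 higher members without spleen replicate 2. Of the 6, 4 were higher in spleen replicate 2 than in replicate 1, as the myeloid markers were. Of these, 3 are receptors that myeloid cells also carry. The 4 had low values, 2.14 to 3.43 in replicate 2. The brighter Cxcr4 (6.43 and 6.31 in replicates 1 and 2) and S1pr1 (6.29 and 6.28) were higher in replicate 1. So few genes do not tell whether RNA of myeloid cells is a source. Camera gave the list an adjusted p of 0.0497, and an adjusted p = 0.216 with an estimated correlation. It lost the list under quantile normalization (0.0578) and median centring (0.0644), with the floors (0.103 and 0.205), without the 40% dimmest probe sets (0.517) and with only the 2 states in the fit (0.13). The same held for array weights (0.068), the replicate block (0.0686) and the median of a gene's probe sets (0.0577), and without any 1 blast replicate, resting replicate 1 or 3 or spleen replicate 2 (0.0505 to 0.147). Beside Cxcr4, S1pr1 was higher by 0.79 ± 0.24 (adjusted p = 0.0424), a call that was lost without either spleen replicate (adjusted p = 0.182 and 0.186), without resting replicate 1 or 2 (0.0796 and 0.0958), without blast replicate 3 (0.0562), with the floors (0.0915 and 0.109) and with the replicate block (0.123). The other S1pr1 probe set differed by 0.11 (adjusted p = 0.19). Ccr2 was at 4.36 ± 0.22 (SD, n = 2) against 3.92 ± 0.27 (SD, n = 4; adjusted p = 0.164, and 0.0483 without resting replicate 2), and Cxcr3 at 5.76 ± 0.11 (SD, n = 2) against 6.42 ± 0.17 (SD, n = 4; adjusted p = 0.121, and 0.00463 with only the 2 states in the fit). Integrins and adhesion molecules had 9 of 30 higher and 2 lower, 12 and 3 adjusted over the list alone (camera adjusted p = 0.0209, adjusted p = 0.216 with an estimated correlation, and 0.07 with a floor at the 20th percentile). There were 4 higher members without spleen replicate 2. Itgb3 was higher by 0.74 ± 0.12, and Ninj1 was at 3.11 ± 0.03 (SD, n = 2) against 2.97 ± 0.07 (SD, n = 4; adjusted p = 0.197). Cytoskeleton and cell motility had 10 of 37 higher and 1 lower, also adjusted over the list alone (camera adjusted p = 3.14e-05, adjusted p = 0.359 with an estimated correlation). S100a11 was up by 2.31 ± 0.22 and Lgals3 by 1.74 ± 0.10. There were 5 higher members without spleen replicate 1 and 6 without spleen replicate 2.

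T cell activation had 5 of 25 genes higher and 1 lower, 5 and 4 adjusted over the list alone (camera adjusted p = 0.371, fry 0.00816), with the activation markers Cd83 and Cd69 up by 1.66 ± 0.16 and 1.28 ± 0.16 and Tnfrsf4 at -1.41 ± 0.19. Il2ra was at 4.38 ± 0.16 (SD, n = 2) against 4.17 ± 0.12 (SD, n = 4; adjusted p = 0.551) and Myc at 4.09 ± 0.10 (SD, n = 2) against 3.87 ± 0.22 (SD, n = 4; adjusted p = 0.762). Of 24 cytokines and chemokines 2 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.371, fry 0.0248). Ccl4 was up by 1.00 ± 0.13 and the chemokine Xcl1 by 0.75 ± 0.09 (adjusted p = 0.0686 with a floor at the 40th percentile), and Ifng was at 4.60 ± 0.05 (SD, n = 2) against 4.07 ± 0.56 (SD, n = 4; adjusted p = 0.294). Of 30 interferon response genes 3 were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.354). Of the 3, the 2 on array A were higher in spleen replicate 2 than in replicate 1, and 7 were called higher without blast replicate 5. Rsad2 was up by 0.58 ± 0.08 (adjusted p = 0.207 with a floor at the 40th percentile). Of 21 T cell identity genes none was higher and only Cd4 was lower, also adjusted over the list alone (-0.60 ± 0.13, adjusted p = 0.00879, and 0.0902 without spleen replicate 2; camera adjusted p = 0.656 for the list, mean -0.08, median 0.02). Of 23 cell death regulators none was higher and 2 were lower, also adjusted over the list alone (camera adjusted p = 0.371). They were Traf1 (-0.46 ± 0.08), not called without spleen replicate 1 (adjusted p = 0.0521), and Casp12 (-0.44 ± 0.10), not called without either spleen replicate (adjusted p = 0.0624 and 0.123).

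Immediate early and stress genes had 13 of 24 members higher and none lower, 17 adjusted over the list alone (camera adjusted p = 1.46e-08, adjusted p = 0.178 with an estimated correlation). There were 6 higher members without spleen replicate 1. Dusp1 was higher by 1.93 ± 0.14, Ier2 by 1.24 ± 0.15 and the NF-kappaB inhibitor Nfkbia by 1.12 ± 0.18. Myeloid markers had 16 of 28 higher and 1 lower, 22 and 1 adjusted over the list alone (camera adjusted p = 6.92e-08, adjusted p = 0.216 with an estimated correlation). Lyz2 was up by 2.22 ± 0.21. There were 9 higher members without spleen replicate 2. MHC class II antigen presentation had 5 of 8 higher and none lower, 6 adjusted over the list alone (camera adjusted p = 3.14e-05, adjusted p = 0.216 with an estimated correlation). RT1-Da was up by 2.22 ± 0.24. B cell markers had 4 of 16 higher and none lower, 12 adjusted over the list alone (camera adjusted p = 7.26e-06 on array B, adjusted p = 0.326 with an estimated correlation). Pou2af1 was up by 0.72 ± 0.14 (adjusted p = 0.103 and 0.296 with the floors at the 20th and 40th percentile) and Cd79b by 0.48 ± 0.07 (0.207 at the 40th). The 4 became 7 under quantile normalization or median centring and 9 without spleen replicate 1.

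Erythroid and platelet markers had 3 of 13 members higher and none lower, 5 adjusted over the list alone (camera adjusted p = 0.000558, adjusted p = 0.216 with an estimated correlation). Alas2 was up by 0.80 ± 0.09 and the platelet factor Pf4 by 0.63 ± 0.11. Under median centring 5 were higher. NK and CD8 T cell markers had 11 of 17 higher and none lower, also adjusted over the list alone (camera adjusted p = 6.92e-08, adjusted p = 0.178 with an estimated correlation). Nkg7 was up by 2.26 ± 0.22, Klrd1 by 1.81 ± 0.17 and Cd8a by 0.83 ± 0.07 (adjusted p = 0.0645 with a floor at the 40th percentile). There were 5 higher members without spleen replicate 2. Thymocyte markers had 4 of 9 higher and 1 lower, 4 and 2 adjusted over the list alone (camera adjusted p = 0.00359, adjusted p = 0.178 with an estimated correlation, and 0.0654 with a floor at the 40th percentile). Cd1d1 was up by 1.04 ± 0.09 and Satb1 at -0.57 ± 0.08. Of 23 stroma and endothelium markers 1 was higher and none lower, also adjusted over the list alone (camera adjusted p = 0.0737, 0.0421 without resting replicate 4 and 0.00713 with fry). It was Acta2, up by 0.29 ± 0.06, not called without spleen replicate 2 (adjusted p = 0.118). Other probe sets of Ak4 (-0.08, adjusted p = 0.331), Calca (-0.55, adjusted p = 0.0638), Pdk4 on array A (-0.30, adjusted p = 0.0788), Idi1 (0.28, adjusted p = 0.415) and Traf1 (-0.01, adjusted p = 0.951) were not called.

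On array A 1148 probe sets were called higher in spleen than in resting cells and 1500 lower, and on array B 450 and 817. Without spleen replicate 1 the counts on array A were 718 and 698 and without spleen replicate 2 they were 679 and 621. On array B 220 were lower without spleen replicate 1, 531 lower without resting replicate 2 and 249 higher without spleen replicate 2. Of the lists tested on both array types, camera called on array A but not on array B quiescence (adjusted p = 0.989, mean -0.04), trafficking receptors (0.55), integrins (0.0838, 0.0444 with a floor at the 40th percentile, 0.0382 without spleen replicate 1 and 0.0291 with fry), cytoskeleton (0.513) and erythroid and platelet markers (0.844).

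The spleen state thus stood apart from both cultured states in part of the genes, such as Nr4a1, Cxcr4, Klf4 and the glycolytic genes. The probe sets higher against both include markers of other cell types, such as S100a9 (3.36 and 3.32), Hbb (2.82 and 2.83) and Lyz2 (2.28 and 2.22). Like these markers, Klf4 was higher in spleen replicate 2 (3.53) than in replicate 1 (3.24), as were 7 of the 9 called quiescence genes. Called higher against both were 588 probe sets on array A and 240 on array B, against 139 and 24.2 for independent lists. Called lower against both were 517 and 267, against 225 and 75.7. At an unadjusted p under 0.05 against both, 926 and 606 were higher and 910 and 717 lower. Data simulated with no change gave 149 and 144 higher and 148 and 142 lower on average. All states were alike in these data, so they do not show the overlap that separate real differences from each state would give. Without spleen replicate 1 the lower counts were 214 and 61, and without spleen replicate 2 the counts on array A were 322 higher and 216 lower and on array B 131 higher. Without resting replicate 2 the lower count on array B was 174. The covariance of the differences across probe sets was 0.0324 on array A against 0.00634 simulated, and 0.0107 on array B against 0.00435. The comparisons were not made on separate spleen replicates, so part of the excess may come from the arrays that both comparisons share.

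Over the genes that separate blasts from resting cells, spleen cells lay between these states. On array A their position was 0.664 ± 0.033 (SD, n = 2) over 822 probe sets higher in resting cells and 0.677 ± 0.0364 (SD, n = 2) over 991 lower ones, where 0 is the blast and 1 the resting level. On array B it was 0.554 ± 0.237 (SD, n = 2) over 272 and 0.645 ± 0.194 (SD, n = 2) over 377. Leaving out single cultured replicates moved the position of the genes lower in resting cells on array A to 0.437 without resting replicate 3 and to 0.765 without blast replicate 5. On array B the genes higher in resting cells gave 0.156 without resting replicate 1 and those lower gave 0.424 without blast replicate 3. Gene groups differed in this, with cell cycle genes between the states and cholesterol and ribosome biogenesis genes near resting cells. For spleen cells the labels give the day after transfer and no day after antigen challenge. In all spleen comparisons, time since challenge, the transfer, the spleen and the sort therefore cannot be told apart.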

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

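The tests of a mislabelled resting array and of a fault of 1 hybridization for blast replicate 5 were chosen only after its values were seen. Samples far from the others of their state were looked for in the blasts and resting cells, by the gap to the nearest other sample as a share of the range. Of 394 such tests 32 stood out, where chance gives about 1 in 20 (19.7), and 16 of the 32 were blast replicate 5.

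Blast replicate 5 stood apart on array A in the means of cell cycle genes (4.74, others 4.93 to 4.99), cell death regulators (3.87, others 3.64 to 3.69) and MHC class II genes (3.82, others 3.38 to 3.49). It was low in Fabp5 (5.45), Nhp2 (4.53), Hspe1 (5.95), Hspd1 (5.96) and Mcm6 (5.21). It was high in Serpinb1a (3.13), Mcl1 (5.13), Apoe (3.33), Epor (4.19), Cxcr4 (5.70), Tsc22d3 (3.57) and S100a11 (4.28). On array B it was low in Aloxe3 (3.99).

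Of the other blasts, replicate 1 was high in Fos (3.25, others 1.63 to 1.84) and Fosb (2.77, others 2.01 to 2.18), and replicate 4 was low in Pdk1 (4.04) and Casp12 (3.21). Resting replicate 4 was low in Tpi1 (5.47), Ckb (4.91), Tob1 (3.05) and the mean of cytokines and chemokines (3.12). Resting replicate 2 was high in Ccr2 (4.32), Ociad2 (4.44), Cenpf (3.36) and the median of all probe sets on array A (3.05, others 3.04). Resting replicate 1 was low in Lgals3 (3.54), and resting replicate 3 was high in the mean of trafficking receptors on array B (3.99). In the 3 prime minus 5 prime signal on array B, blast replicate 2 was high for actin (0.0663) and blast replicate 1 low for hexokinase (0.444). These flags are within the range that chance gives.

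The first pattern is the place of blast replicate 5 between the other blasts and resting cells, at 0.394 on array A and 0.401 on array B. A resting array under a wrong name would lie near 1, and a single faulty hybridization would not repeat, whereas the deviations on the 2 array types correlated with r = 0.97. Degraded RNA would raise the 3 prime signal of actin or Gapdh above that of every other blast, and its largest excess was -0.0385. Fewer dividing cells would not give the whole pattern, since its position was 0.137 on array A and 0.0693 on array B for cell cycle genes, against 0.753 and 0.851 for ribosome biogenesis. An earlier or later time after challenge may be a source. Apart from fewer dividing cells, no biological explanation was tested.

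The second pattern is the rise of markers of other cell types in the sorted spleen samples, such as S100a9 at 5.14 ± 0.38 (SD, n = 2), Lyz2 at 5.33 ± 0.79 (SD, n = 2) and RT1-Da at 5.19 ± 0.26 (SD, n = 2). Normalization between arrays left 16 or more of the called myeloid markers higher than in resting cells, which argues against it. If other spleen cells in the sorted sample contribute their RNA, their markers should move together between replicates. All 16 called myeloid markers (a share of 1) were higher in spleen replicate 2, by 0.526 ± 0.0598 (SE over markers) on average. Lists without markers also moved 1 way. Of the called genes, 8 of 8 in respiration and 9 of 10 in cytoskeleton were higher in replicate 1, and 3 of 3 interferon genes in replicate 2. Genes on 1 pair of arrays are not replicates, so moving together does not by itself point to other cells. On array A, 14 of 14 myeloid, 5 of 5 MHC class II and 3 of 3 erythroid markers were higher in replicate 2. So were 7 of 10 NK and CD8 and 3 of 4 thymocyte markers, against 33 of 98 called genes of the other lists. The values of replicate 2 were spread less on array A (SD 1.04 against 1.08 in replicate 1). The 98 genes were not matched to the markers in brightness, so the contrast may in part follow brightness. Array B (17 of 18 of all lists) cannot tell markers apart. These marker counts share genes, with Cd8a and Cd8b in both the NK and CD8 and the thymocyte list. Fcgr3a is in both the myeloid and the NK and CD8 list. Other spleen cells in the sorted sample remain a candidate source for the myeloid, MHC class II and erythroid markers, which the replicate counts cannot settle. Expression of some of these genes by the T cells themselves, as for Nkg7, which blasts express, stays open and was not tested.

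The third pattern is the rise of immediate early genes in spleen cells. Normalization between arrays left 12 or more of the 13 called members higher than in resting cells. RNA of other spleen cells would make them follow the myeloid markers between replicates. They went the other way on average, by -0.136 ± 0.0676 (SE over 13 genes), only just past 2 SE, with 11 of 13 higher in spleen replicate 1. The other 2 were Dusp1 (4.10 in spleen replicate 1, 4.52 in replicate 2) and Jun. Of the 98 called genes outside the marker lists on array A, these 13 included, 65 were higher in replicate 1. Genes on 1 pair of arrays are not replicates, so this cannot decide the question. Handling during the sort and signals received in the spleen are both bound to the spleen state in this design, so either may be the source.

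The count of probe sets called between resting cells and blasts was set against other splits of the 9 cultured samples. On array A, 1 of 100 splits, the real one, called as many (5894, highest other drawn 5), and on array B also 1 of 100 (3292, highest other 2829). A share of 1 of 100 is the smallest that this test can give, so chance is unlikely for both but not excluded. The highest other on array B put blast replicate 5 with the resting cells, and the same split, not among those drawn on array A, called 5252 there. This points to a structure of the samples in which blast replicate 5 lies between the states.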

How the results depend on the processing

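The alternatives were all chosen before the data were examined, and none of the tests here was chosen after the result was seen. No called difference of a named gene and no called list shift changed its direction under these alternatives. The direction of other probe sets was not followed. The share of higher calls for resting cells against blasts on array A went from 52.4% to 47.4% under median centring. Fry gave the opposite sign to camera for 2 uncalled lists on array B, integrins between resting cells and blasts (adjusted p = 0.671) and quiescence between spleen and resting cells (adjusted p = 0.998).

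With a floor at the 20th percentile, the position of spleen cells on array A was 0.608 and 0.567 (genes higher and lower in resting cells), 528 probe sets on array B were lower in spleen than resting cells and 168 lower against both cultured states. With a floor at the 40th percentile these were 0.571, 0.552, 417 and 129, and 309 on array A were lower against both. On array B 293 were then higher than in resting cells, and 507 higher and 877 lower than in blasts. Without the 40% dimmest probe sets, 158 on array B were higher against both. With only the 2 compared states in the fit, 511 were higher and 852 lower in spleen cells than in blasts on array B, where fewer samples estimate the spread. Exchanging the cultured samples used to choose and to measure the genes gave a position of 0.612 for genes higher in resting cells on array A. Otherwise the cause was not tested.

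With an estimated inter-gene correlation camera called 0 lists in each comparison and array type. It found 1, 7 and 5 lists on array A and 1, 2 and 2 on array B at an unadjusted p under 0.05. With the preset correlation it called 8, 18 and 14 on array A and 4, 10 and 3 on array B. Fry called 14 lists between resting cells and blasts on array A and 7 on array B.

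Leaving out each replicate in turn gave these ranges. For resting cells against blasts 2710 to 3317 probe sets were higher and 2461 to 3088 lower on array A, and 1317 to 1792 and 1290 to 1913 on array B. For spleen cells against blasts these were 1171 to 2319 and 1228 to 2955 on array A, and 406 to 975 and 485 to 1823 on array B. For spleen against resting cells they were 679 to 1451 and 621 to 1950 on array A, and 249 to 545 and 220 to 981 on array B. Against both states, 322 to 687 were higher and 214 to 702 lower on array A, and 131 to 263 and 61 to 370 on array B. Called lists numbered 8 to 10, 17 to 18 and 13 to 15 on array A, and 4 to 5, 8 to 11 and 3 to 4 on array B. The position was 0.636 to 0.847 and 0.437 to 0.765 on array A, and 0.156 to 0.722 (10 of 11 settings gave a value) and 0.424 to 0.827 on array B. A lone spleen sample is assumed to vary like the other groups.

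With the replicate number as a block, 3231 and 2978 probe sets were called for resting cells against blasts on array A, 2318 and 2699 for spleen cells against blasts and 1179 and 1500 for spleen against resting cells. On array B these were 1593 and 1702, 824 and 1519, and 361 and 545. With it Cxcr3, Cd4, Ninj1 and Myc were called between spleen cells and blasts (adjusted p = 0.00515, 0.022, 0.00712 and 9.01e-06), and S1pr1 was not called between spleen and resting cells (adjusted p = 0.123). The block fits blast replicate 5 exactly and so includes leaving it out. Without that replicate limma also called Myc and Ninj1 (adjusted p = 0.000875 and 0.0214). Deviations of arrays with one number correlated between states with r from -0.25 to 0.16, so the values give no sign that the numbers pair the samples. Arrays of different numbers were not compared, so a pairing is not excluded.

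Of 6071 values of named genes under an alternative, 5860 kept their side of the threshold, 197 lost the call and 14 gained it. Of 2469 list shifts these were 2329, 100 and 40. Of 2760 counts of list members 307 moved by over 1.5 times, and of 240 counts of probe sets with a difference of 1 unit 7 did.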

Other observations

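The gene families in this part were chosen after the data were seen, and their tests are descriptive. Mitochondrial ribosomal proteins were lower in resting cells than in blasts in 60 of 70 measured genes and higher in 1 (camera adjusted p = 3.99e-16, adjusted p = 0.28 with an estimated correlation). In spleen cells 43 were lower than in blasts and none higher (camera adjusted p = 1.34e-10, adjusted p = 0.301 with an estimated correlation). Against resting cells 13 were higher in spleen cells and 1 lower, or 22 and 1 under quantile normalization (camera adjusted p = 0.000424, adjusted p = 0.501 with an estimated correlation). Proteasome subunits were lower than in blasts in 30 of 36 genes in resting cells (camera adjusted p = 1.22e-08, adjusted p = 0.301 with an estimated correlation) and in 22 in spleen cells (camera adjusted p = 2.8e-06, adjusted p = 0.347 with an estimated correlation), with 1 higher in resting cells under quantile normalization. Of 16 aminoacyl tRNA synthetases 14 were lower than in blasts in each state (camera adjusted p = 1.42e-05 and 2.87e-06, adjusted p = 0.308 and 0.301 with an estimated correlation), with 1 higher in resting cells under quantile normalization. All 8 chaperonin subunits were lower in each (camera adjusted p = 1.42e-05 and 4.25e-05, adjusted p = 0.28 and 0.301 with an estimated correlation). Cytosolic ribosomal proteins were lower in 17 of 44 genes in resting cells and 11 in spleen cells, but under quantile normalization 4 were higher and 13 lower in resting cells and 1 higher and 9 lower in spleen cells.

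Some families of regulators had members higher in spleen cells. Of 14 Kruppel-like factors 7 were higher than in blasts (camera adjusted p = 0.00024, adjusted p = 0.0992 with an estimated correlation) and 4 were higher than in resting cells (camera adjusted p = 0.0129, adjusted p = 0.148 with an estimated correlation), with none lower. Of 17 regulators of G protein signalling 5 were higher than in blasts (camera adjusted p = 0.0044, adjusted p = 0.12 with an estimated correlation) and 3 higher than in resting cells (camera adjusted p = 0.0185, adjusted p = 0.148 with an estimated correlation), with none lower. All 5 measured Gimap GTPases of T cell survival were higher in resting cells than in blasts and 3 in spleen cells, or 4 under quantile normalization. Between spleen and resting cells limma called none of the 5 (mean -0.07). Kinesins went both ways, with 12 of 26 lower and 3 higher in resting cells than in blasts, 13 lower and 1 higher in spleen cells than in blasts (camera adjusted p = 0.0211, adjusted p = 0.301 with an estimated correlation), and 10 higher and 4 lower in spleen than in resting cells.

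One hypothesis was that the lower glycolytic genes of spleen cells may go with less oxygen stress than in dense culture, so that other targets of the hypoxia factor HIF should be lower against both cultured states. Of 26 such genes outside the fixed lists 8 were lower and 1 higher in each comparison. Their mean difference was -0.30 against blasts (camera adjusted p = 0.00903) and -0.272 against resting cells (camera adjusted p = 0.00637), and the adjusted p was 0.468 in both with an estimated correlation. The values go with the hypothesis, and a lower glycolytic demand without any change of oxygen is not excluded.

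A further hypothesis was that glucocorticoids in the animal may raise Tsc22d3 and other targets of their receptor against both cultured states. Of 16 targets 8 were higher than in blasts and none lower (mean 0.31, camera adjusted p = 0.00119, adjusted p = 0.0992 with an estimated correlation). In culture, resting cells also had 6 of them higher than blasts and 1 lower (mean 0.24, camera adjusted p = 0.0558, adjusted p = 0.228 with an estimated correlation). Against resting cells 5 were higher and 2 lower, with a mean of 0.0652 (camera adjusted p = 0.133), which leaves the hypothesis open.

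Another came from the clock genes Dbp, Nr1d1 and Nr1d2, which rose in resting cells against blasts by 1.66 ± 0.14, 1.64 ± 0.19 and 1.43 ± 0.10 (adjusted p = 6.39e-06, 6.96e-05 and 1.52e-06). If a shared clock phase is a possible explanation, the Per genes, Tef and Hlf should follow, and their mean difference was 0.141, which decides nothing. On a wider clock list, 5 of 12 measured genes were higher in resting cells than in blasts and 1 was lower. Camera gave an adjusted p of 0.0174, and an adjusted p = 0.194 with an estimated correlation. In spleen cells 4 were higher than in blasts and none lower (camera adjusted p = 0.0044, adjusted p = 0.148 with an estimated correlation). The prediction did not rest on this list. The hour of sampling is not used here.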
